A study of Mus musculus with 4 samples.

How the data were processed

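The deposited unit is UMI counts per gene and cell barcode, together with counts of 2 barcoded antibodies against CD45.1 and CD45.2, in 1 filtered matrix per library. Per the submitters' processing notes, these matrices came from Cell Ranger 3.1.0 with the mm10 genome. Per the labels, the 4 libraries hold donor T cells sorted from recipient spleens 8 days after induction of graft-versus-host disease. They differ in the genotype of the regulatory T (Treg) cells transferred besides conventional T cells: wild type, CD226 knockout, TIGIT knockout and double knockout. Each library is a pool of 3, and the record leaves open whether these were recipients, donors or both. Each genotype has 1 library. Per the file headers, the wild-type and CD226-knockout libraries came from lane 3, and the TIGIT-knockout and double-knockout libraries from lane 4. The lane number therefore follows TIGIT status, while CD226 contrasts lie within a lane.

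Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. Donor origin was read from protein: a mixture of 3 Gaussian components with 1 shared variance was fitted per library to the log2 ratio of CD45.1 to CD45.2 counts, each plus 1. A cell was assigned at a posterior of at least 0.9, and cells with a ratio beyond p 0.001 of every component were left out. The component with mostly CD45.2 was called Treg donor, the one with mostly CD45.1 conventional donor, and the middle one, with both antibodies, was set apart, since it can hold bone-marrow progeny and doublets. A 2-dimensional mixture with free covariances had been tried before, and the form was changed after the antibody counts and RNA values by class, Foxp3 among them, had been seen; the earlier form was kept as an alternative. Conventional cells were divided into CD4 and CD8 by whether Cd4 or Cd8a plus Cd8b1 UMIs were more numerous, and cells with neither or with equal counts were not resolved. Scrublet, run per library with an expected doublet rate of 0.08, marked 0, 0, 1 and 0 barcodes, so it did not work on these cells and its calls were not used.

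UMIs were summed per class and library and scaled to the class total as CPM. Intervals are exact 95% Poisson or Clopper-Pearson intervals and hold counting error only. Shares of cells with a UMI were also taken after thinning each cell to 2000 UMIs. Log2 ratios used a pseudocount of 1 CPM. The contrasts were CD226 loss with TIGIT present (CD226 knockout over wild type), CD226 loss with TIGIT absent (double knockout over TIGIT knockout), TIGIT loss with CD226 present (TIGIT knockout over wild type), TIGIT loss with CD226 absent (double knockout over CD226 knockout), and double loss (double knockout over wild type). No test was made between genotypes, because cells of 1 library are not replicates.

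Before the files were opened, 20 gene lists were fixed: Treg identity, Th1 and inflammatory cytokines, Th2/Th17/Tfh, cytotoxicity, inhibitory receptors, naive and memory genes with Foxo1 targets, IL-2 and STAT5, TCR activation, mTORC1 and glycolysis, proliferation, interferon response, apoptosis, homing, stress and dissociation, and markers of B and plasma cells, myeloid cells, neutrophils, erythroid cells, NK cells, and gamma-delta and NKT cells. Members with a mean of at least 5 CPM entered, and a list with fewer than 3 such members got no value. The median log2 ratio of a list was placed as a percentile among 10000 random lists matched on mean expression, each member drawn from its 100 nearest genes, and its interval came from 1000 Poisson draws of the counts. In all, 265 list values were computed, of which 143 lay in the outer 5% of their random lists. Random lists ignore that members of a real list vary together, so an extreme percentile is common and describes these libraries only, and the shares from simulated lists do not carry over to real ones. The lists the report leads with, apart from Treg identity, were picked after all values had been seen.

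Treg-donor cells were compared with CD4 conventional-donor cells on the 8 class sums with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood F-test, library as block, Benjamini-Hochberg, adjusted p of at most 0.05), with n = 4 libraries. Cd226 and Tigit were left out of its calls because the libraries differ in both genes by design. The SE printed with a log2 fold is the size of the fold over the square root of its F statistic. It is not a standard error fitted by the model. The test was tested on simulated data: with 50 genes changed at each of 1.5-, 2-, 3- and 4-fold among 10628, it found 58%, 76%, 94% and 96% of them, and 7 of 169 called genes were false. The simulation changed 200 genes in all and had no differences between libraries. The real comparison called 4548 genes, so these rates need not carry over. The list method was tested on simulated data as well: lists with a true log2 shift of 0.18, 0.20 and 0.19 in the Treg, CD4 and CD8 classes gave medians of 0.16, 0.20 and 0.18, and of 100 lists without a shift per class 5%, 2% and 2% lay in the outer 5%.

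Genes were named by rules fixed before the files were opened. For each class and each genotype factor these were the genes with a mean of at least 20 CPM and at least 50 UMIs whose ratio had the same sign in both contrasts of the factor, ranked by the smaller size, 10 each way in Treg-donor cells and 5 each way in CD4 and CD8 cells. TCR and immunoglobulin segments, ribosomal protein and mitochondrial genes, and gene models without a name were left out of the ranking. Foxp3, Cd226, Tigit and the 2 highest and 2 lowest members of each list were always to be given, and for the edgeR test the 15 largest folds each way with the same sign in 4 libraries, with the same exclusions applied. Of the list members, the text prints most of those of the lists the report leads with, for CD226 loss, and not every gene these rules picked is printed.

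Clusters served only to find non-T and proliferating cells and never set a class: 2000 variable genes without Foxp3, Cd226, Tigit and receptor segments, 30 principal components, 15 neighbours and Leiden at resolution 1 gave 20 clusters, of which 7, 17 and 18 were led by non-T genes (seed 7). Clusters 1, 3, 8, 11 and 12 were taken as proliferating, by at least 2 proliferation markers among the 10 leading genes or a median log2 fold of these markers of at least 0.5. Clusters 8 and 11 entered by the median alone (0.52 and 0.74). Cluster 8, led by Ccr9, Cysltr1 and Xist, had no such marker among its 10 leading genes, and cluster 11 had 1. Dividing cells of other clusters stayed in, such as cluster 10 with Mki67 in 94.7% of cells. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and DESeq2 1.42.0. Chromosomes came from GENCODE vM21, in which 30934 of the matrix's gene IDs were found.

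Alternatives planned beforehand were TMM scaling, no cell filter, a stricter filter (1000 genes, 5% mitochondrial UMIs), thinned cells, no proliferating clusters, a posterior of 0.99, no filter on low genes, a pseudocount of 5 CPM and, for the edgeR test, DESeq2, no count filter, no block and each library left out in turn. Alternatives chosen after seeing the data were the 2-dimensional mixture, removal of the highest doublet scores, removal of clusters led by non-T genes, removal of cells with the other donor's sex-linked transcripts, and Treg-donor cells with more Cd4 than Cd8 UMIs. Added later still were list values with the UMI shares of clusters held equal between libraries, over clusters with at least 20 cells of the class in each library: 15 clusters in CD4 cells, 13 in CD8 cells, and only clusters 0 and 2 in Treg-donor cells, which held 70.3%, 70.4%, 63.7% and 58.1% of them. Because the clusters were formed from the same transcripts, a smaller value at equal shares does not tell a change in cell shares from a change within cells. TCR and immunoglobulin repertoires and splicing were not analysed here.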

Results

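The sequenced cells were donor T cells from the spleens of irradiated BALB/c mice with acute graft-versus-host disease, in which transferred Treg cells carried or lacked the activating receptor CD226 and the inhibitory receptor TIGIT, while the conventional T cells were wild type throughout. Of the barcodes, 7654 (wild type), 9045 (CD226 knockout), 10383 (TIGIT knockout) and 9058 (double knockout) passed the cell filter, with a median of 9026.5, 7911, 6972 and 8055 UMIs. Antibody counts assigned 96.7%, 96.9%, 96.2% and 98.1% of them to a donor class. Treg-donor cells numbered 360, 324, 460 and 382, CD4 conventional cells 2893, 3192, 3232 and 2841, and CD8 conventional cells 2253, 2708, 3057 and 3444. Each genotype was 1 library, so no contrast between single libraries has a replicate check. CD226 loss is seen in 2 contrasts that share no library, but no test across both was made, and the values between genotypes are descriptions with counting error only.

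Cd226 transcripts were nearly absent from Treg-donor cells of both CD226-knockout genotypes. The gene encodes an activating receptor that shares its ligands with TIGIT. In Treg-donor cells Cd226 stood at 31.3 CPM [24.5, 39.5] in wild type, 2.93 [0.953, 6.85] in CD226 knockout, 32.1 [24.9, 40.7] in TIGIT knockout and 4.32 [1.98, 8.21] in double knockout. The ratios were 0.0937 [0.0295, 0.229] with TIGIT present and 0.135 [0.0591, 0.272] with TIGIT absent. A Cd226 UMI was seen in 15.6%, 1.54%, 12% and 2.09% of Treg-donor cells (6.94%, 0.651%, 7.39% and 1.67% after thinning). The wild-type CD4 conventional cells beside them had 66.7, 72.5, 64.2 and 66.5 CPM and a Cd226 UMI in 42.2%, 42.1%, 36.1% and 39.7% of cells, at median depths of 9001, 8039.5, 7037 and 7787 UMIs against 5388, 4788.5, 3946.5 and 4623 in Treg-donor cells. Tigit in Treg-donor cells was 9.26 [5.73, 14.2], 5.28 [2.42, 10.0], 8.62 [5.11, 13.6] and 5.77 [2.98, 10.1] CPM, with intervals that overlap between all genotypes. The matrices do not say where in the gene the reads fall or which part is deleted, and a 3' tag outside a deleted part checks nothing, so the TIGIT genotype rests on the labels.

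Sex-linked transcripts separated the donors as the antibodies did. Xist, the transcript that silences an X chromosome in female cells, was found without any Y-linked UMI in 89.4%, 88.0%, 87.0% and 86.9% of Treg-donor cells, whereas 66.3%, 62.3%, 57.4% and 65.2% of conventional cells held a Y-linked UMI without Xist. Treg donors were therefore female and conventional donors male. Within the Treg-donor class, 37.2%, 29.0%, 29.8% and 28.5% of cells lay in a cluster led by Ccr9, Cysltr1 and Il4, and 33.1%, 41.4%, 33.9% and 29.6% in a cluster led by Foxp3, Ikzf2 and Ctla4. Of all Treg-donor cells, in these clusters or not, 2.5%, 4.32%, 4.78% and 5.76% held more Cd8 than Cd4 UMIs.

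Treg-donor cells made up the smallest share where only CD226 was absent. They were 4.87% of assigned cells in wild type [4.39, 5.38], 3.69% in CD226 knockout [3.31, 4.11], 4.61% in TIGIT knockout [4.20, 5.04] and 4.30% in double knockout [3.89, 4.74]. CD8 cells were 43.8% [42, 45], 45.9% [44.6, 47.2], 48.6% [47.4, 49.9] and 54.8% [53.6, 56.0] of conventional cells resolved as CD4 or CD8, highest beside double-knockout Treg cells, and 24.5%, 26.4%, 31.7% and 24.5% of conventional cells were not resolved. The libraries with TIGIT absent were also those of lane 4.

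**Figure D1:**
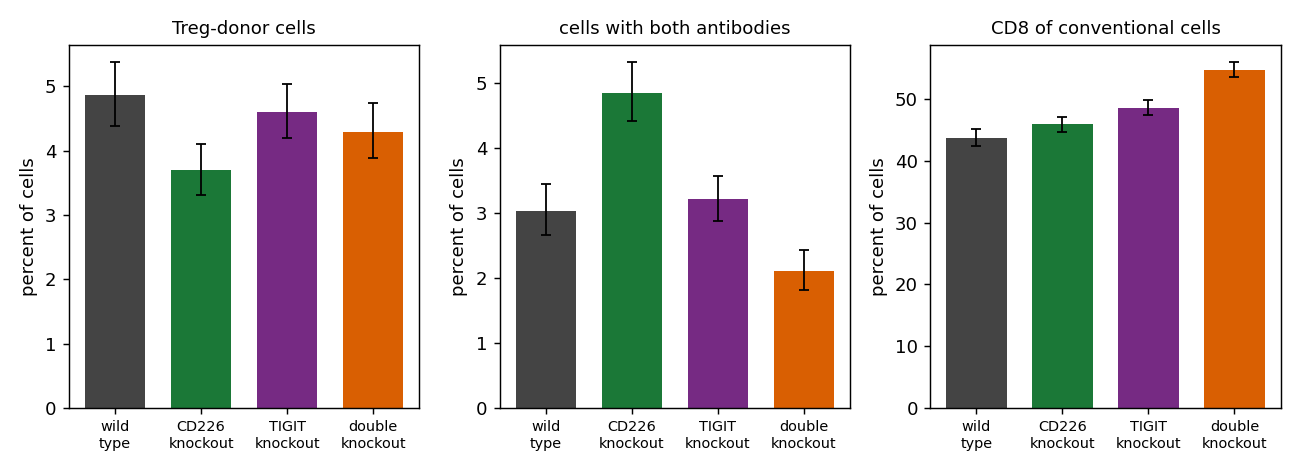
Treg-donor cells and cells with both antibodies as percent of assigned cells, and CD8 cells as percent of resolved conventional cells, in each library. Bars are percent and error bars 95% Clopper-Pearson intervals (counting error only).

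Foxp3, the transcription factor that defines Treg cells, lay somewhat higher in Treg-donor cells without CD226, with intervals that spanned no difference. Its level was 54.7 CPM [45.5, 65.2] in wild type, 65.2 [53.6, 78.5] in CD226 knockout, 47.9 [39, 58.2] in TIGIT knockout and 58.6 [48.7, 70.0] in double knockout. CD226 loss gave ratios of 1.19 [0.914, 1.55] with TIGIT present and 1.22 [0.932, 1.61] with TIGIT absent. TIGIT loss gave 0.876 [0.666, 1.15] with CD226 present and 0.90 [0.690, 1.17] with CD226 absent, and double loss 1.07 [0.828, 1.39]. Among Treg-donor cells with more Cd4 than Cd8 UMIs, the log2 ratio for CD226 loss with TIGIT absent turned from 0.29 to -0.16. A Foxp3 UMI was found in 24.7%, 26.9%, 17.2% and 24.1% of Treg-donor cells against 1.56%, 0.783%, 0.774% and 0.774% of the deeper CD4 conventional cells. After thinning, which left out 14, 17, 54 and 22 Treg-donor cells and 13, 11, 30 and 12 CD4 cells, the shares were 9.54%, 12.4%, 9.11% and 11.9% against 0.451%, 0.189%, 0.344% and 0.212%.

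**Figure D2:**
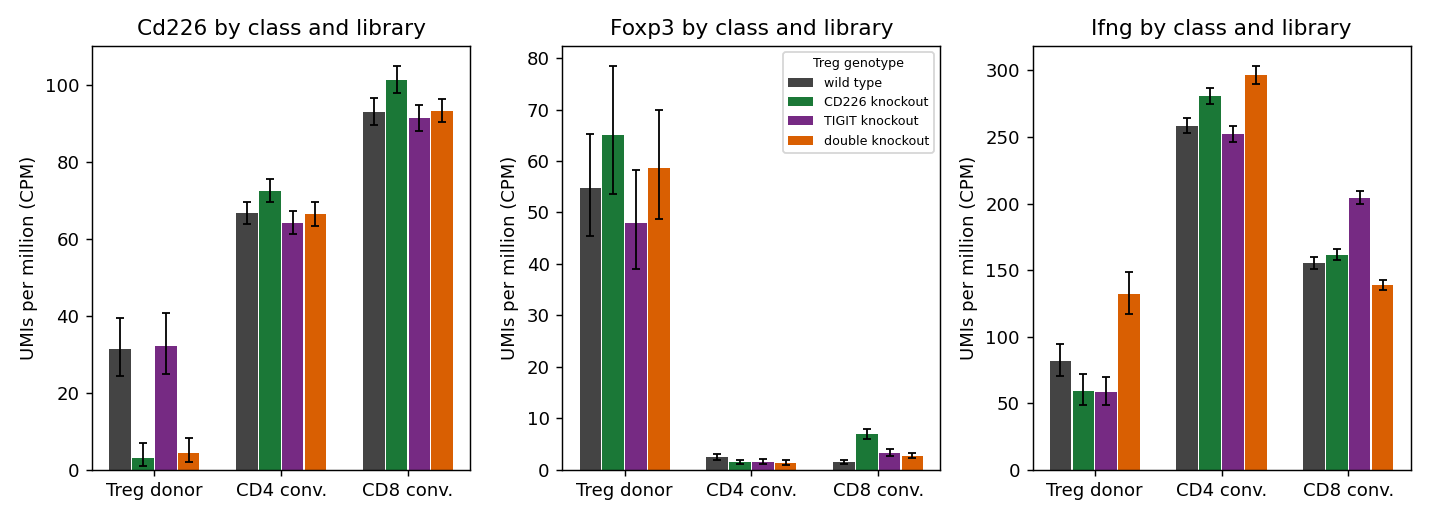
Cd226, Foxp3 and Ifng in CPM of summed UMIs, by cell class and library. Error bars are exact Poisson 95% intervals (counting error only).

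Proliferation genes lay lower in Treg-donor cells without CD226, in both TIGIT backgrounds. The list holds cell-cycle genes such as Mki67, Cdk1 and Ccna2, DNA-synthesis enzymes such as Tyms, and Rrm2. Percentiles here describe these libraries and are no test, since 143 of 265 list values lay in the outer 5% of their random lists. The median log2 ratio of the list was -0.27 [-0.33, -0.21] with TIGIT present, percentile 0 of the random lists with 0 of 21 genes higher, and -0.17 [-0.25, -0.11] with TIGIT absent, percentile 0.015 with 2 of 21 higher. Mki67 went from 284 CPM in wild type to 205 in CD226 knockout, and from 322 in TIGIT knockout to 289 in double knockout. Ccna2 (122 to 89.8 and 127 to 99.9 CPM), Cdk1 (159 to 119 and 175 to 143) and Tyms (202 to 160 and 227 to 162) lay lower in both. The replication genes Mcm3 (ratios 0.934 and 1.04) and Mcm2 (0.928 and 0.985) were the highest members. The clusters taken as proliferating went both ways: clusters 1, 3, 11 and 12, with proliferation markers among their leading genes, held 3.06%, 6.48%, 5% and 7.33% of Treg-donor cells in the order wild type, CD226 knockout, TIGIT knockout and double knockout, and the Ccr9-led cluster 8 held 11.9%, 5.86%, 14.3% and 10.5%. Within clusters 0 and 2 at equal shares the medians were -0.23 and -0.18. The list also lay lower, by smaller medians, in the wild-type CD4 and CD8 conventional cells of the same libraries, as given below. The direction was therefore not confined to cells that lack CD226.

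Genes of resting and memory T cells lay higher in the same contrasts. Naive and memory genes with Foxo1 targets, which include the IL-7 receptor gene Il7r and the migration regulator Klf2, had median log2 ratios of 0.25 [0.06, 0.43] at percentile 99.95 with TIGIT present and 0.15 [0.02, 0.28] at percentile 97.6 with TIGIT absent, 9 of 12 genes higher each time. Il7r was 168, 331, 198 and 223 CPM in wild type, CD226 knockout, TIGIT knockout and double knockout, Klf2 370, 535, 403 and 500, Slamf6 118, 161, 134 and 154, and Bcl2 88.6, 119, 103 and 114. In the same order, 1.94%, 4.01%, 2.61% and 6.28% of Treg-donor cells (7, 13, 12 and 24 cells) lay in the Il7r-led cluster 16. That cluster was 96.9% conventional-donor cells. The class averages do not separate more such cells from higher levels per cell. Satb1 (0.846 and 0.946) and Id3 (0.558 and 0.711) were the lowest members. Under the stricter cell filter the list with TIGIT absent turned to -0.06. Glycolytic and mTORC1 genes stood at -0.16 [-0.22, -0.07] (percentile 0.34) with TIGIT present, which became -0.06 without the proliferating clusters and -0.00 within clusters 0 and 2 at equal shares. With TIGIT absent they stood at -0.06 [-0.13, 0.00], at percentile 21.3 and so within the range of random lists. Tpi1 stood at 226, 163, 198 and 170 CPM and Pkm at 779, 649, 719 and 626 CPM. Hk2 (1.83 and 1.28) and Slc7a5 (1.03 and 1.29) were its highest members and Slc2a3 (0.961 and 0.640) the lowest beside Tpi1. With TIGIT absent the value was -0.16 on thinned cells and -0.14 within clusters 0 and 2 at equal shares. Both lists had the same directions in the wild-type CD4 and CD8 conventional cells of the same libraries, as given below. These directions were therefore not confined to cells that lack CD226 either.

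Treg identity genes did not share a direction between the TIGIT backgrounds. This list, with Foxp3, Ikzf2, Ctla4 and Il10 among 23 measured genes, had a median of 0.06 [-0.04, 0.16] at percentile 89.1 for CD226 loss with TIGIT present and -0.15 [-0.24, -0.06] at percentile 0.265 with TIGIT absent. Klrg1, a marker of terminally differentiated Treg cells, stood at 56.9, 105, 99.1 and 73.0 CPM in wild type, CD226 knockout, TIGIT knockout and double knockout, and Il10 at 36.6, 60.5, 66.1 and 47.1. Lrrc32, which presents latent TGF-beta, was 19.4, 18.8, 29.7 and 16.3 CPM. Ebi3, a subunit of IL-35, was 37.0, 26.4, 41.2 and 23.1 CPM, lower without CD226 in both backgrounds. Itgae (1.81 and 0.907) and Icos (1.36 and 1.12) were the highest members. Under the stricter filter the median with TIGIT absent was -0.04.

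Single genes that lay highest without CD226 in Treg-donor cells included receptors and signalling genes. Like all genes named by rank, they are the extremes of these ratios, so their counting intervals are no test. Of 4960 genes with a mean of at least 20 CPM, 54.6% had the same sign in both CD226 contrasts and 52.9% in both TIGIT contrasts. Gramd3 was also among the highest genes of wild-type CD4 cells, and Rsrp1 of wild-type CD8 cells, in the same contrasts. Tnfrsf25, a costimulatory receptor of Treg cells, was 15.4, 41.1, 13.9 and 29.8 CPM, ratios 2.66 [1.75, 4.12] with TIGIT present and 2.15 [1.36, 3.46] with TIGIT absent. Klrd1, the CD94 chain of NKG2 receptors, had ratios of 2.82 [1.93, 4.17] and 1.73 [1.28, 2.36], with 52.1% of the UMIs of its richest library in 5 cells, and Slamf1 1.57 [1.15, 2.16] and 1.89 [1.41, 2.57]. Rsrp1 had 1.48 [1.33, 1.66] and 1.58 [1.42, 1.76], Gramd3 1.66 [1.10, 2.53] and 1.53 [1.03, 2.29], Nlrc3 1.56 [1.10, 2.21] and 1.47 [1.06, 2.06], AC149090.1 2.07 [1.52, 2.86] and 1.52 [1.11, 2.09], Pink1 1.56 [1.06, 2.31] and 1.58 [0.960, 2.63], and Pecam1 1.5 [0.956, 2.35] and 1.76 [1.08, 2.90]. Hbb-bt, also among the highest 10, and all of the lowest 10 (S100a9, S100a8, Ngp, Camp, Lcn2, Lyz2, Chil3, Fcer1g, Gcg and Anxa1) had over 50% of the UMIs of their richest library in 5 cells. In the wild-type library 3951 of 3960 neutrophil-gene UMIs came from 1 cell, and in the TIGIT-knockout library 3145 of 3154.

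TIGIT loss, confounded with the lane, went with higher proliferation genes in Treg-donor cells. The list median was 0.14 [0.09, 0.19] with CD226 present (percentile 99.9, 18 of 21 genes higher) and 0.25 [0.18, 0.32] with CD226 absent (percentile 100, 20 of 21 higher). Without the proliferating clusters the value with CD226 present turned to -0.0077, and on thinned cells it was 0.29. At a posterior of 0.99 the value with CD226 absent was 0.14. Treg identity stood at 0.08 [-0.02, 0.20] and -0.19 [-0.29, -0.08], and naive and memory genes at 0.09 [-0.04, 0.20] and -0.06 [-0.19, 0.08]. Under the stricter filter the first identity value was -0.05, and on thinned cells the first naive and memory value was -0.09. For mTORC1 and glycolysis the medians were -0.08 [-0.14, -0.02] and -0.05 [-0.13, 0.03]. Cells lacking both receptors stood at -0.05 [-0.12, 0.01] for proliferation, which turned to 0.12 with the 2-dimensional mixture, at -0.02 [-0.11, 0.13] for Treg identity, at 0.31 [0.13, 0.46] for naive and memory genes and at -0.14 [-0.23, -0.07] for mTORC1 and glycolysis. The naive and memory value for double loss turned to -0.08 under the stricter filter.

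Among single genes of Treg-donor cells, AA467197 and Usp18, which trims the interferon-induced modifier ISG15 from proteins, lay lower with TIGIT loss and were spread over many cells. AA467197 was 90.8, 93.9, 45.5 and 56.7 CPM in wild type, CD226 knockout, TIGIT knockout and double knockout, ratios 0.501 [0.388, 0.642] with CD226 present and 0.604 [0.472, 0.771] with CD226 absent. Usp18 had 0.651 [0.419, 1.0] and 0.614 [0.401, 0.933], and Pink1 0.585 [0.356, 0.943] and 0.590 [0.391, 0.884]. The other 7 of the lowest 10 had over 50% of the UMIs of their richest library in 5 cells: the effector genes Ly6c2 (59.3%; ratios 0.471 and 0.379), Gzmc (60.3%; 0.498 and 0.337) and Ccl1 (64.7%; 0.555 and 0.140), and the haemoglobin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2. Nol11 ranked first by the smaller of its ratios, 1.71 [1.21, 2.43] and 1.80 [1.25, 2.62]. Gpr65 (1.6 and 1.59), Cep55 (1.48 and 1.72), Egr1 (1.46 and 2.06), Spc25 (1.67 and 1.44), Dcp1b (1.66 and 1.43) and Abhd17c (1.51 and 1.42) followed, and Gcg, Anxa1 and Lyz2 were concentrated in few cells.

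Wild-type CD4 conventional cells transferred with CD226-deficient Treg cells had more transcripts of the chemokine genes Ccl3, Ccl4 and Ccl5 and fewer of Ccl1. Ccl3 and Ccl4 encode chemokines that draw in leukocytes and were 125, 198, 137 and 256 CPM and 175, 269, 210 and 349 CPM in the order wild type, CD226 knockout, TIGIT knockout and double knockout. Their ratios for CD226 loss in the Treg donor were 1.59 [1.52, 1.65] and 1.87 [1.79, 1.94] for Ccl3, and 1.53 [1.48, 1.59] and 1.66 [1.61, 1.72] for Ccl4. Ccl1 was 224, 166, 296 and 200 CPM, ratios 0.742 and 0.677. In the library with most UMIs of each gene, 5 cells held 17.4% of those of Ccl3, 17.7% of Ccl4 and 18.1% of Ccl1. The counting intervals of these genes therefore understate the spread between cells. Th1 and inflammatory cytokine genes had medians of 0.11 [0.08, 0.14] with TIGIT present and 0.13 [0.09, 0.19] with TIGIT absent, at percentiles 100 and 99.99 with 13 of 20 genes higher each time. Ccl5 (ratios 1.37 and 2.94) was highest beside Ccl3, and Il12rb1 (0.90 and 0.819) and Il2 (0.594 and 0.943) were lowest. For cytotoxicity the medians were 0.29 [0.23, 0.33] with 12 of 14 genes higher and 0.09 [0.06, 0.13] with 11 higher, with Klrd1 at 159, 202, 136 and 167 CPM, Klrc1 (1.57 and 1.14) and Gzmk (1.26 and 1.42) highest, and Gzmb (0.739 and 1.03) and Gzma (0.857 and 0.738) lowest. TIGIT loss gave -0.06 and -0.01 for the Th1 list and -0.06 and -0.16 for cytotoxicity, and double loss 0.14 and 0.06. At equal cluster shares the values for CD226 loss were 0.09 and 0.08 for the Th1 list and 0.21 and 0.04 for cytotoxicity, and the log2 ratios of Ccl3 were 0.69 and 0.66. Under a posterior of 0.99 the Th1 value for double loss was 0.015, on thinned cells 0.07, and the cytotoxicity value for CD226 loss with TIGIT absent was 0.15 on thinned cells.

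Naive and memory genes lay higher and growth genes lower in CD4 conventional cells with CD226 loss in the Treg donor. For naive and memory genes the medians were 0.13 [0.08, 0.16] and 0.15 [0.08, 0.19], with Slamf6 (95.4, 131, 96.3 and 119 CPM) and Il7r (1.57 and 1.03) highest and Foxo1 (1.02 and 0.920) and Satb1 (0.971 and 0.724) lowest. Proliferation stood at -0.08 [-0.10, -0.06] and -0.14 [-0.17, -0.12], and mTORC1 and glycolysis at -0.11 [-0.15, -0.09] and -0.08 [-0.10, -0.06], with Tpi1 at 267, 222, 266 and 231 CPM. Aurka (0.941 and 0.840) and Rrm2 (0.942 and 0.775) were the lowest proliferation genes, Cenpa (0.964 and 1.06) and Stmn1 (0.996 and 1.02) the highest; Aldoa (0.939 and 0.847) was lowest beside Tpi1, and Ddit4 (1.40 and 0.875) and Asns (1.02 and 1.05) were highest. The Il7r-led cluster 16 held 12.1%, 16.7%, 11.7% and 15.5% of CD4 cells, and cluster 15, led by Ccl5 and with Gzmk, 1.28%, 2.32%, 0.743% and 2.08%. At equal cluster shares the values for CD226 loss were 0.08 and 0.10 for naive and memory genes, -0.03 and -0.08 for proliferation, and -0.12 and -0.09 for mTORC1 and glycolysis. TIGIT loss gave -0.01 and -0.12 for naive and memory genes, 0.04 and -0.02 for proliferation, and -0.01 and 0.00 for mTORC1 and glycolysis; double loss gave 0.10, -0.13 and -0.10. Without proliferating clusters the proliferation value with TIGIT absent was -0.32, and on thinned cells the one with TIGIT present was -0.13.

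Genes lowest in CD4 cells with CD226 loss in the Treg donor included the gut-homing receptor Ccr9 and the ligand-activated factor Ahr. Ccr9 was 25.9, 12.1, 29.0 and 15.2 CPM, ratios 0.468 [0.412, 0.531] and 0.525 [0.464, 0.593]; Ahr had 0.742 [0.692, 0.797] and 0.724 [0.674, 0.777]. The Ccr9-led cluster 0 held 7.47%, 4.35%, 8.73% and 5.53% of CD4 cells, but Ccr9 helped to form that cluster, so these shares do not separate fewer such cells from less Ccr9 per cell. Lgals7 had 0.713 and 0.481, and Fam213a 0.666 and 0.716, and Ccl1, given above, was the remaining one of the lowest 5. Besides Ccl3 and Ccl4, Gramd3 was among the highest (1.41 and 1.40), and S100a9 and S100a8 had over 50% of the UMIs of their richest library in 5 cells. With TIGIT loss the highest were Ccl1 (1.32 and 1.20), Ccl4 (1.20 and 1.30), Mt1 (1.67 and 1.20), Runx1 (1.18 and 1.23) and Ddx23 (1.15 and 1.15). Lowest were Gramd3 (0.777 and 0.770), the granzyme gene Gzma (0.805 and 0.693), Hist1h2ae (0.842 and 0.820), Hist1h2ap (0.60 and 0.843) and Prkab1 (0.847 and 0.781). Genes were picked for the same sign in both contrasts. Of 4886 genes in CD4 cells, 56.6% had this for CD226 loss but only 46.3% for TIGIT loss.

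Wild-type CD8 cells showed more Klrk1 and cytotoxicity transcripts and fewer glycolytic ones beside CD226-deficient Treg cells. Klrk1, which encodes the activating receptor NKG2D, was 143, 226, 179 and 233 CPM in wild type, CD226 knockout, TIGIT knockout and double knockout, ratios 1.58 [1.53, 1.64] and 1.30 [1.26, 1.35]. Cytotoxicity genes had medians of 0.16 [0.13, 0.19] and 0.08 [0.06, 0.11], 10 of 14 genes higher each time, with Gzmk (0.832 and 1.86) highest beside Klrk1, and Gzmb (0.844 and 1.21) and Cst7 (1.02 and 0.905) lowest. For mTORC1 and glycolysis the medians were -0.17 [-0.20, -0.14] with 1 of 20 genes higher and -0.10 [-0.12, -0.09] with 3 higher; Tpi1 was 323, 246, 291 and 268 CPM and Pgam1 285, 237, 273 and 235, the lowest members, and Ddit4 (1.43 and 0.707) and Pfkp (0.973 and 0.946) the highest. Proliferation stood at -0.04 [-0.05, -0.02] and -0.09 [-0.11, -0.07], and naive and memory genes at 0.10 [0.04, 0.14] and 0.11 [0.05, 0.15]. Mcm2 (0.842 and 0.934) and Rrm2 (0.899 and 0.822) were lowest and Cenpa (1.01 and 1.10) and Stmn1 (1.02 and 1.06) highest in the former list, Id3 (0.864 and 0.914) and Satb1 (0.884 and 0.690) lowest and Il7r (1.58 and 1.17) and Slamf6 (1.09 and 1.16) highest in the latter. On thinned cells the naive and memory value with TIGIT present was 0.017. Cluster 15, led by Ccl5 and Ifit1 and with Gzmk, held 4.97%, 9.08%, 3.89% and 6.79% of CD8 cells. At equal cluster shares the values for CD226 loss were 0.16 and 0.00 for cytotoxicity, -0.16 and -0.09 for mTORC1 and glycolysis, -0.02 and -0.07 for proliferation, and 0.07 and 0.12 for naive and memory genes, and the log2 ratios of Klrk1 0.61 and 0.24. TIGIT loss gave 0.02 and -0.06 for cytotoxicity, -0.07 and -0.01 for mTORC1 and glycolysis, 0.02 and 0.00 for proliferation, and 0.02 and -0.02 for naive and memory genes. Double loss gave 0.09, -0.16, -0.03 and 0.03.

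S100a4, a calcium-binding protein of effector and memory cells, and Tox, a regulator of exhausted T cells, were among the genes highest in CD8 cells with CD226 loss in the Treg donor. S100a4 had ratios of 1.58 [1.55, 1.6] and 1.38 [1.36, 1.40], Tox 1.33 [1.21, 1.47] and 1.52 [1.39, 1.66], Apobec2 1.63 and 1.75, and Rsrp1 1.32 and 1.62. Lowest were Ass1 (0.739 and 0.770), Wdr75 (0.736 and 0.813), Cd6 (0.817 and 0.793), the chaperone gene Hsp90aa1 (0.822 and 0.796) and Pim3 (0.780 and 0.819). With TIGIT loss Ccl1 (1.70 and 1.32), Sfn (1.24 and 1.26), Pwwp2a (1.17 and 1.23) and Ptpn4 (1.23 and 1.16) were highest, with Igkc, whose UMIs lay in few cells. Of the Ccl1 UMIs of its richest library, 38.1% lay in 5 cells. Gstp1 (0.666 and 0.804), Gadd45b (0.800 and 0.803), Trim12a (0.831 and 0.833), Rnf114 (0.822 and 0.848) and Apobec2 (0.788 and 0.847) were lowest. Of 4847 genes in CD8 cells, 56.3% had the same sign in both contrasts for CD226 loss but only 42.0% for TIGIT loss.

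**Figure D3:**
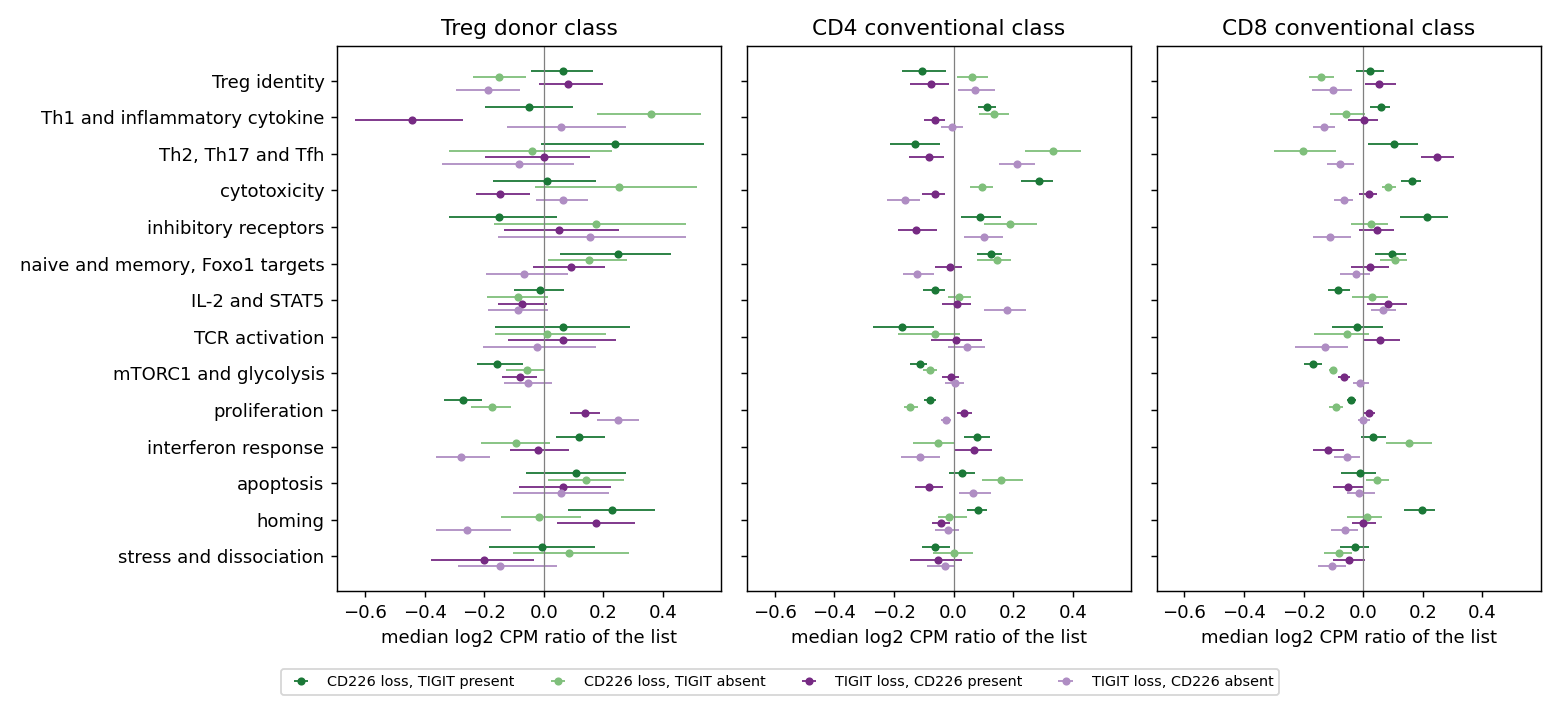
Median log2 ratio of 14 gene lists in Treg-donor, CD4 conventional and CD8 conventional cells for CD226 loss and TIGIT loss in either background. Bars are intervals from Poisson draws of the counts (counting error only).

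The Treg-donor class had higher levels of Foxp3 and of most Treg identity genes than CD4 conventional cells. The values are class averages, as 28.5% to 37.2% of its cells lay in the Ccr9-led cluster 0 and 29.6% to 41.4% in the Foxp3-led cluster 2. Of 10789 genes tested with edgeR (quasi-likelihood, library as block, Benjamini-Hochberg), 2273 were higher and 2275 lower in Treg-donor cells. The classes also differ in donor sex, donor mice, form of CD45 (CD45.2 against CD45.1) and day of transfer. These differences hold in every library, so the test does not separate them from cell type. Foxp3 stood at 56.6 ± 7.23 CPM in Treg-donor cells and 1.68 ± 0.502 in CD4 cells (SD, n = 4), a log2 fold of 5.05 ± 0.17 (SE), edgeR Benjamini-Hochberg adjusted p of 2.61e-10, higher in 4 of 4 libraries. Of the Treg identity list 21 of 24 genes were higher and 0 lower, also when adjusted over the list alone. Lrrc32 was 65.3-fold higher, Itgae, the integrin CD103, 16.0-fold, the Ikaros-family factor Ikzf2 12.7-fold, the STAT5 target Socs2 11.1-fold, Il10 4.94-fold, Ctla4 4.84-fold and the IL-2 receptor gene Il2ra 2.02-fold.

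Interferon-response genes were uniformly higher and proliferation genes uniformly lower in Treg-donor cells than in CD4 conventional cells. All 18 interferon-response genes were higher, with Iigp1 12.1-fold, Ifit1 4.94-fold and Isg15 3.65-fold. All 21 proliferation genes were lower, with Rrm2 at 0.533 and Mki67 at 0.559 of the CD4 level. CD4 conventional cells had to hold more Cd4 than Cd8 UMIs, a rule not put on Treg-donor cells. It was met by 181 of 360, 148 of 324, 209 of 460 and 165 of 382 Treg-donor cells in wild type, CD226 knockout, TIGIT knockout and double knockout. The list counts were not repeated with the rule on both sides, so its part in them was not checked. Th1 and inflammatory cytokine genes were lower in 12 of 20 cases and higher in 4 (13 and 4 adjusted over the list alone). Ifng was 83 ± 34.6 against 272 ± 20.5 CPM (SD, n = 4), a log2 fold of -1.78 ± 0.13 (SE), edgeR Benjamini-Hochberg adjusted p of 3.00e-07, lower in 4 of 4 libraries. The T-bet gene Tbx21 stood at 0.462 and Il2 at 0.347 of the CD4 level, while the chemokine gene Ccl5 was 6.78-fold higher. Of the naive and memory genes 5 were higher and 4 lower (5 and 5 adjusted over the list alone), with Il7r 3.14-fold higher, and Id3 at 0.258 and Tcf7 at 0.439. Mostly lower were mTORC1 and glycolysis genes, 11 against 4 (12 and 5 adjusted over the list alone), and cytotoxicity genes, 7 against 4, with Gzmb 2.83-fold higher but Klrk1 at 0.217.

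The genes with the largest folds included Treg genes and genes of donor sex. Higher in all 4 libraries were Xist (510-fold) and Tsix (28.7-fold), both on the X chromosome. Nckap5 (295-fold), Rln3 (68.4-fold from 2 CD4 UMIs), Lrrc32 (65.3-fold), Foxp3 (33.2-fold) and She (29.0-fold) were higher in all 4 as well. So were the gelatinase gene Mmp9 (26.3-fold), Vill (25.1-fold), Ncmap (23.4-fold), Dgat2 (21.6-fold), Rin2 (19.1-fold), Pon3 (18.9-fold), the tissue-repair factor Areg (18.4-fold) and Slc43a1 (18.2-fold). These are edgeR folds without intervals, and several rest on few pooled UMIs. Treg-donor against CD4 UMIs were 132 and 5 for Nckap5, 19 and 8 for She, and 12 and 8 for Rin2. They were 24 and 15 for Dgat2 and 20 and 14 for Slc43a1. Among the lowest, pooled UMIs gave CD4 over Treg-donor ratios of 70.3 [12.6, 2779] for Uty from 1 Treg UMI, 32.6 [17.7, 68.0] for Ddx3y, 31.9 for Eif2s3y and 13.6 for Kdm5d, all Y-linked. Dapl1 (23.4 [7.98, 114] from 3 UMIs), Exph5 (18.9 [3.36, 748] from 1 UMI) and Ptprk (16.9 [5.75, 82.0] from 3 UMIs) were likewise lower, as were Map1b, Kif5a and Ank3, each with 1 Treg UMI. Onecut2, Mmp10, Nkd1 and Armcx2 had 0 Treg UMIs, so they were at least 4.66-, 4.20-, 3.84- and 3.14-fold lower. Cd4, Cd8a and Cd8b1 helped to set the CD4 class, so their folds are not given.

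**Figure D4:**
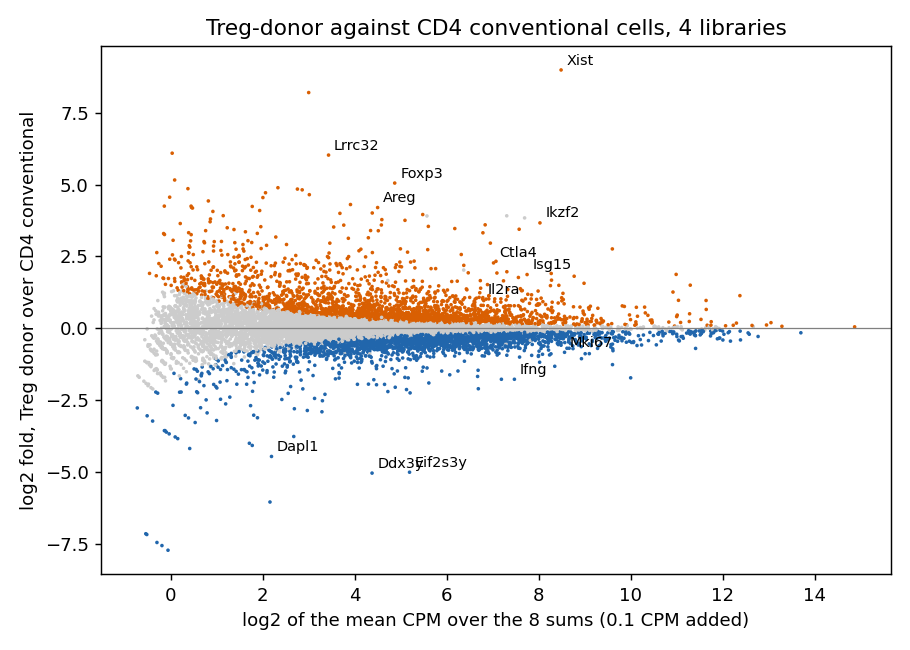
Log2 fold of Treg-donor over CD4 conventional cells against log2 mean CPM over 8 class sums (0.1 CPM added), 1 point per gene. Orange points were higher and blue points lower by edgeR with Benjamini-Hochberg adjustment, grey points were not called.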

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

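The size bound of 0.1 for opposite list values, the choice of Ifng and of Foxp3 in CD8 cells, the tests on Foxp3 in CD8 cells and the test of proliferation against conventional RNA were chosen after the values had been seen; the predictions for proliferation against depth and against removal of cells with a Y-linked UMI were written before these were run. None of the differences between backgrounds or libraries below was tested, because each genotype has 1 library.

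Values of the same loss pointed in opposite directions in the 2 backgrounds for several lists, each with a counting interval that excluded 0. Homing genes in Treg-donor cells stood at 0.17 for TIGIT loss with CD226 present and -0.26 with CD226 absent. Th2/Th17/Tfh genes in CD4 cells stood at -0.13 for CD226 loss with TIGIT present and 0.33 with TIGIT absent, and in CD8 cells at 0.10 and -0.20. Inhibitory receptors in CD4 cells stood at -0.12 for TIGIT loss with CD226 present and 0.10 with CD226 absent. The opposition was lost in 3 of these 4 pairs under at least 1 setting each: the first homing value turned to -0.03 in cells with more Cd4 than Cd8 UMIs, the first CD4 Th2/Th17/Tfh value to 0.02 without proliferating clusters, and the first CD8 Th2/Th17/Tfh value to -0.05 without a filter on low genes. Ifng in Treg-donor cells had log2 ratios of -0.46 for CD226 loss with TIGIT present and 1.16 with TIGIT absent, at 82.0, 59.3, 58.4 and 132 CPM in wild type, CD226 knockout, TIGIT knockout and double knockout. The 5 richest cells held 40.3%, 40.6%, 32.8% and 33.8% of its UMIs, so its counting intervals understate the spread between cells.

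Cells carrying both antibodies, which the report leaves out, made up 3.03%, 4.85%, 3.20% and 2.10% of assigned cells in wild type, CD226 knockout, TIGIT knockout and double knockout. Of these cells 58.5%, 68.9%, 53.4% and 45.5% held Xist and no Y-linked UMI, and 20.5%, 14.1%, 23.4% and 24.6% held both. More Cd8 than Cd4 UMIs were found in 52.2%, 69.6%, 40.9% and 37.4% of them.

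Foxp3 was found in CD8 conventional cells at 1.47, 6.85, 3.29 and 2.66 CPM, a log2 ratio of 1.67 for CD226 loss with TIGIT present and -0.23 with TIGIT absent. Of the 106 CD8 cells with a Foxp3 UMI in the CD226-knockout library, 72.6% held a Y-linked UMI and 2.83% held Xist, and Ikzf2 stood at 117 CPM against 20.9 in the other CD8 cells of that library. Ikzf2 was likewise higher beside Foxp3 in the other libraries (71.6, 132 and 154 CPM), and Cd4 stood at 43.8 CPM in these 106 cells against 24.4 in the rest, so some may be doublets with CD4 cells. Free RNA of Treg-donor cells, read from Xist, accounted for 6.79% of the measured Foxp3 level. This excludes it as the main source only if free RNA holds Foxp3 and Xist in the ratio of Treg-donor cells. Depth per cell did not account for the share of cells with Foxp3. After thinning, 1.26% of CD8 cells in that library held a Foxp3 UMI against 0.401%, 0.428% and 0.643% elsewhere. CPM is already scaled to depth, and the CD8 cells of that library were not the deepest (median 10051.5 UMIs against 11799 in wild type). Thinning could therefore hardly have shown depth as the cause. Doublets with CD4 conventional cells were excluded as the main source, since those cells held 1.45 CPM in that library, below the 6.85 of the CD8 class. CD8 cells without a Cd4 UMI had 6.54 CPM [5.54, 7.66] against 1.47, 2.97 and 2.18 elsewhere. That subset is a weaker guide, because CD4 cells can lack a Cd4 UMI. In cluster 5, where 2.99% of cells held Cd8a, 53.7% held Cd4. Without cluster 3, which had the deepest cells and often both Cd4 and Cd8a, the CD8 levels were 1.22, 5.93, 2.23 and 1.95 CPM. A hypothesis is that conventional-donor CD8 cells had begun to express Foxp3 in the recipients of that library; protein staining of CD8 cells in several mice per genotype would test it.

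Lower proliferation genes in Treg-donor cells without CD226 were weighed against depth and against contaminating cells. After thinning, the higher of both medians was -0.24, past the bound predicted if depth per cell were not the cause. Medians of summed UMIs scaled to CPM hardly depend on depth per cell, and thinning mainly evens the weight of cells. The test could therefore hardly have shown depth as the cause, and it decides little. Y-linked UMIs put the share of conventional RNA in the class at 3.48%, 2.85%, 3.58% and 3.83%. That share accounts for 4.46% of the median with TIGIT present and 1.82% with TIGIT absent, but for up to 29.3% and 28.8% at the ends of the counting intervals that favour it. The bound for exclusion, under 25%, was not met, so a part played by conventional cells remains open. Leaving out cells with a Y-linked UMI gave -0.20 as the higher of both medians, past the bound predicted if conventional cells were not the cause. It kept 351 of 360, 321 of 324, 451 of 460 and 371 of 382 cells. Because so few cells were taken away, and conventional cells can lack a Y-linked UMI, this result was not taken to decide the question. Also open are differences between recipients, since each genotype has 1 pooled library. The list lay lower in the wild-type conventional cells of the same libraries as well, so the direction was shared across donors. A count of dividing Treg cells in single mice would test the difference.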

How the results depend on the processing

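The order of libraries is wild type, CD226 knockout, TIGIT knockout and double knockout; values are median log2 ratios of lists unless another unit is given, and TIGIT present, TIGIT absent, CD226 present and CD226 absent name the background of the loss. A value counts as unchanged where it stayed inside the counting interval of the main value. That held for 54 of 55 alternative values of Foxp3 in Treg-donor cells, for 22 of 40 class shares and for 2 of 2 values of Cd226. Of the named genes of the edgeR comparison, 472 of 472 alternative values kept their call and direction, not counting settings in which a gene was no longer tested. These genes were chosen as the largest called folds with the same sign in 4 libraries, so high retention was largely built in. For the lists the report leads with, 236 of 260 values were unchanged in Treg-donor cells, 275 of 300 in CD4 cells and 223 of 240 in CD8 cells, and for the remaining lists 794 of 910, 635 of 720 and 741 of 840. Removal of doublets gave nothing separate because the caller marked almost none, and the cluster resolutions of 0.6 and 1.6 were not run because no class came from clusters. No paired analysis of genotypes was made, as each has 1 library and the labels give no replicate numbers that libraries share. An additive fit of CD226 loss with the lane as block would leave 1 residual degree of freedom and was not run. The comparison of donors was blocked by library.

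Planned settings moved the following values. With thinned cells, in Treg-donor cells proliferation was -0.31 (CD226 loss, TIGIT absent) and 0.29 (TIGIT loss, CD226 present), mTORC1 and glycolysis -0.25 and -0.16 (CD226 loss, TIGIT present and absent), -0.018 and 0.041 (TIGIT loss, CD226 present and absent), and naive and memory genes 0.35 (CD226 loss, TIGIT absent) and -0.088 (TIGIT loss, CD226 present). In CD4 cells thinning gave Th1 -0.045 (TIGIT loss, CD226 absent) and 0.070 (double loss), cytotoxicity 0.20 and 0.15 (CD226 loss, TIGIT present and absent), mTORC1 and glycolysis -0.11 (CD226 loss, TIGIT absent) and 0.044 (TIGIT loss, CD226 absent), and proliferation -0.13 (CD226 loss, TIGIT present) and 0.0050 (TIGIT loss, CD226 present). CD8 cells gave Th2/Th17/Tfh -0.049 for double loss, which turned its direction, cytotoxicity 0.12 (CD226 loss, TIGIT absent), 0.048 and -0.11 (TIGIT loss, CD226 present and absent), mTORC1 and glycolysis -0.12 (CD226 loss, TIGIT absent) and -0.013 (TIGIT loss, CD226 present), naive and memory genes 0.017 and proliferation -0.056 (CD226 loss, TIGIT present), and proliferation 0.026 (TIGIT loss, CD226 absent).

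Without proliferating clusters, Treg-donor proliferation with TIGIT loss and CD226 present turned to -0.0077, and mTORC1 and glycolysis with CD226 loss and TIGIT present was -0.061. In CD4 cells Th2/Th17/Tfh with CD226 loss and TIGIT present turned to 0.018, Th1 was 0.16 (CD226 loss, TIGIT present), cytotoxicity -0.022 and -0.24 (TIGIT loss, CD226 present and absent) and 0.022 (double loss), and proliferation -0.11 and -0.32 (CD226 loss), 0.062 and -0.054 (TIGIT loss) and -0.17 (double loss). In CD8 cells inhibitory receptors for double loss turned to -0.019, cytotoxicity was 0.12 and 0.052 (CD226 loss), -0.032 (TIGIT loss, CD226 absent) and 0.11 (double loss), and proliferation -0.066 (CD226 loss, TIGIT present), 0.042 (TIGIT loss, CD226 absent) and -0.054 (double loss).

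Under the stricter cell filter, Treg-donor naive and memory genes turned to -0.060 (CD226 loss, TIGIT absent) and -0.080 (double loss), and Treg identity was -0.044 (CD226 loss, TIGIT absent) and -0.049 (TIGIT loss, CD226 present). CD4 Th1 was 0.045 (TIGIT loss, CD226 absent), cytotoxicity 0.22 (CD226 loss, TIGIT present) and proliferation -0.12 (CD226 loss, TIGIT absent). CD8 cells were then 45.5%, 48.0%, 50.9% and 56.9% of resolved conventional cells, and Treg-donor cells 5.61%, 5.82% and 5.08% of the 3 resolved classes in wild type, TIGIT knockout and double knockout, against 6.54%, 6.82% and 5.73% in the main processing. At a posterior of 0.99, that share was 5.81%, 4.32%, 5.60% and 5.17%, CD4 Th1 was -0.11 (TIGIT loss, CD226 present) and 0.015 (double loss), and Treg-donor proliferation 0.14 (TIGIT loss, CD226 absent). Without a filter on low genes, CD8 TCR activation turned to 0.0059 (TIGIT loss, CD226 absent) and CD8 Th2/Th17/Tfh to -0.046 (CD226 loss, TIGIT present) and -0.010 (double loss).

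Settings chosen after the data were seen moved others. With the 2-dimensional mixture, CD8 shares were 41.2%, 43.9% and 45.7% in wild type, CD226 knockout and TIGIT knockout, Treg-donor proliferation was 0.22 and 0.36 (TIGIT loss) and turned to 0.12 (double loss), CD4 Th1 was -0.11 (TIGIT loss, CD226 present) and 0.019 (double loss), CD8 Th2/Th17/Tfh turned to -0.027 and cytotoxicity was 0.068 (double loss), and CD8 mTORC1 and glycolysis was -0.089 (CD226 loss, TIGIT absent). Among Treg-donor cells with more Cd4 than Cd8 UMIs, Foxp3 was -0.16 (CD226 loss, TIGIT absent), cytotoxicity turned to 0.13 and homing to -0.031 (TIGIT loss, CD226 present), homing turned to -0.025 and identity was -0.12 (double loss), mTORC1 and glycolysis was 0.078 (TIGIT loss, CD226 absent), naive and memory genes were -0.13 and -0.25 (TIGIT loss) and 0.073 (double loss), and proliferation was -0.35 (CD226 loss, TIGIT present). Without the highest doublet scores, CD8 shares were 42.3%, 44.2%, 47.1% and 52.9%, and CD4 proliferation was -0.055 (CD226 loss, TIGIT present).

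For the comparison of Treg-donor with CD4 cells, leaving out each library in turn gave 1774 to 1989 genes higher and 1868 to 2102 lower. The fewest calls came from thinned cells, with 1518 higher and 1441 lower, and from Treg-donor cells with more Cd4 than Cd8 UMIs, with 1654 and 1669 and 2 calls opposite to those of the main processing. DESeq2 called 1852 and 1836, all 3688 shared with edgeR, no count filter 2102 and 2751, and no block 2241 and 2218.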

Other observations

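Interferon-response, chemokine and cytokine genes of Treg-donor cells had different values in the 2 backgrounds in which a receptor was lost, and the differences were not tested. Interferon-response genes, which include Ifit1 and Isg15, had a median of 0.12 [0.04, 0.20] for CD226 loss with TIGIT present and -0.09 [-0.21, 0.02] with TIGIT absent, and for TIGIT loss -0.02 [-0.11, 0.08] and -0.28 [-0.36, -0.18] with 0 of 18 genes higher. Th1 and inflammatory cytokine genes stood at -0.05 [-0.20, 0.10] and 0.36 [0.18, 0.53] for CD226 loss, and at -0.44 [-0.63, -0.27] and 0.06 [-0.12, 0.28] for TIGIT loss. Ccl3 was 101, 45, 119 and 270 CPM and Ccl4 265, 81.6, 135 and 320 CPM in Treg-donor cells of wild type, CD226 knockout, TIGIT knockout and double knockout, and Ifit1 56.9, 78.1, 63.2 and 48.5 CPM. Of the Ccl3 UMIs, 72.2%, 75.3%, 92.3% and 46.7% lay in 5 cells. Cytotoxicity genes stood at 0.01 and 0.25 for CD226 loss and -0.15 and 0.06 for TIGIT loss; the value with CD226 present turned to 0.13 in cells with more Cd4 than Cd8 UMIs.

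The other T-cell lists of Treg-donor cells had these values. For CD226 loss with TIGIT present and absent, then TIGIT loss with CD226 present and absent, the medians were 0.24, -0.04, 0.00 and -0.08 for Th2/Th17/Tfh, -0.15, 0.17, 0.05 and 0.16 for inhibitory receptors, -0.01, -0.09, -0.07 and -0.09 for IL-2 and STAT5, and 0.06, 0.01, 0.06 and -0.02 for TCR activation. Apoptosis stood at 0.11, 0.14, 0.07 and 0.06, homing at 0.23, -0.02, 0.17 and -0.26, and stress and dissociation at -0.01, 0.09, -0.20 and -0.15. In CD4 cells interferon response stood at 0.08, -0.05, 0.07 and -0.11, TCR activation at -0.17, -0.06, 0.01 and 0.05, and IL-2 and STAT5 at -0.06, 0.02, 0.01 and 0.18. In CD8 cells interferon response stood at 0.03, 0.15, -0.12 and -0.05, inhibitory receptors at 0.21, 0.03, 0.05 and -0.11, and homing at 0.20, 0.01, -0.00 and -0.06.

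Lists of other cell types had large medians in the Treg-donor class. B and plasma cell genes stood at 3.89, -0.59, 0.28 and -3.79, myeloid genes at 0.13, -1.44, 0.42 and -0.21, neutrophil genes at -7.52, -6.33, -0.36 and 0.00, and erythroid genes at 4.46, 0.48, -0.89 and -4.93, in the same order. NK-cell genes stood at 0.58, 0.73, 0.17 and 0.24 in CD8 cells and had fewer than 3 measured members in the other classes, as did the gamma-delta and NKT list in every class. The 5 richest cells of the wild-type and TIGIT-knockout libraries held 99.9% of the neutrophil-gene UMIs of their class, a test predicted before it was run, and this fits a few neutrophils or doublets with them. In the CD226-knockout library 1694 of 1738 erythroid-gene UMIs came from 1 cell.

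In the edgeR comparison of Treg-donor with CD4 cells, the lists not given above changed as follows, with Benjamini-Hochberg adjustment over all genes tested. Higher and lower genes numbered 6 and 3 of 11 for Th2/Th17/Tfh (Gata3 2.07-fold and Il4 2.54-fold higher, Il21 at 0.174 of the CD4 level), 5 and 5 of 12 for inhibitory receptors, 8 and 1 of 15 for IL-2 and STAT5, 5 and 1 of 15 for TCR activation, 3 and 1 of 12 for apoptosis, 7 and 4 of 12 for homing (Ccr9 10.0-fold higher, Itgb1 at 0.399) and 4 and 3 of 9 for stress and dissociation. Adjusted over the list alone these counts were the same. Markers of other cells were higher in 3 of 3 cases for B and plasma cells, 5 of 10 for myeloid cells, 1 of 4 for neutrophils (2 adjusted over the list alone), 2 of 5 for erythroid cells (3 adjusted over the list alone) and 2 of 4 for gamma-delta and NKT cells, and 1 of 4 NK-cell genes was lower.

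Groupings of the class sums were compared after the result had been seen. Each library gives a Treg-donor and a CD4 sum, and the 8 splits that part every library are too few for a share under 0.05; with the block the real one called 4548 genes and the highest other 3. The 35 splits of the 8 sums into 4 and 4 without a block ignore this pairing; there the real one called 4459 genes and the highest other 0.

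Across genes, which are not independent replicates, the log2 ratios of CD226 loss in both backgrounds correlated at 0.477 in Treg-donor cells, 0.488 in CD4 cells and 0.152 in CD8 cells, and those of TIGIT loss at 0.0742, -0.113 and -0.186. Without clusters led by non-T genes, a comparison added after seeing the data, the values were 0.126, 0.292 and 0.158 for CD226 loss and 0.119, -0.104 and -0.179 for TIGIT loss.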
